A study of Solanum lycopersicum x Solanum pennellii and Solanum lycopersicum with 7 samples.

How the data were processed

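Leaf RNA was measured by sequencing in 3 libraries of IL2-6, 3 libraries of IL3-2 and 1 library of M82. Samples were grouped by the line in their titles, and the replicate numbers come from the same titles. The deposited values for the introgression lines are raw gene counts, 1 table per library with 34725 gene identifiers and no row without a gene. For M82, the deposited file lists variant records with a quality score, depth fields and a genotype, and it names chromosomes of the SL2.50 tomato build. The submitters' processing notes list CASAVA 1.8.2, Trimmomatic, TopHat2, SAMtools 1.9, HTSeq and edgeR, without a role or order. The build and annotation behind the counts, the strand setting of the counting and the variant caller are not given in the sources used here. The labels name both an unstranded single-end kit and a stranded paired-end kit and do not say which libraries used which, so counts of genes that overlap on opposite strands, and of near-identical copies, are uncertain.

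Library totals were 18479252 to 21320790 counts in IL2-6 and 28828109 to 40146308 in IL3-2. Replicates were compared before they were averaged. A chi-square test of the counts over genes with at least 20 counts gave 2.33 to 11.22 per degree of freedom between libraries of the same line, so no pair agreed within sampling noise and each library was counted as a replicate.

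Genes were kept with edgeR's filterByExpr with the line as group, which left 20823. Counts were scaled with TMM factors, which were 0.928 to 0.958 in IL2-6 and 1.053 to 1.064 in IL3-2. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with the line as the only term, and calls used a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are IL2-6 minus IL3-2, and 2-fold calls have an absolute log2 fold change of at least 1 in addition. The estimated biological coefficient of variation was 5.9%. Levels are CPM, counts per 1000000 of the TMM-scaled library total. Only the summed levels of the chromosome 1 block differ: they are per 1000000 of the raw library total, over all listed genes between its borders. A fold against a line without counts was computed against 3 counts over that line's libraries, and a fold against 1 count has a 95% exact binomial interval for counting error.

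The test was tried on simulated counts for the same 20823 genes with 200 genes changed. It recovered 76.1% of the genes changed 1.5-fold, 89.6% of those changed 2-fold and 95.5% of those changed 4-fold, and 21 of its 195 calls were false. DESeq2 1.42.0 recovered 76.1%, 88.1% and 95.5% with 15 false of 188 calls, and limma-voom (limma 3.58.1) recovered 76.1%, 91% and 95.5% with 17 false of 192. With each tool the false share of the calls was above the limit set for the adjusted p. Far fewer genes were changed than were called in the data, so these rates describe the simulation only.

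Chromosome and gene order were read from the identifiers, whose digits number the chromosome and the order along it by the convention of the tomato annotation. Genes with chromosome number 0, which are not placed, were left out of the chromosome comparisons. Calls on chromosome 2 and on chromosome 3 were compared with the 10 other numbered chromosomes by two-sided Fisher's exact tests (scipy 1.17.1), as fixed before the data were examined. Counts per 50 tested genes were described without a test. A scan was added after the bins had been seen. It searched each chromosome on a grid of 10 genes for the block of at least 50 genes richest in 2-fold calls, by a likelihood ratio against the rest of that chromosome, and compared it with 1000 shuffled gene orders. The scan was tried on a simulated chromosome with and without a planted block. Its borders are accurate to the grid at best. Since a scan picks the richest block, segments were also placed on every other gene and measured on the genes between, and the reverse, so that no gene helped to choose the segment it was measured in. Differences of medians between a segment and the other chromosomes have bootstrap intervals from 2000 resamples of genes.

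Variant records of M82 were counted as deposited and past a quality of 30 and a depth of 10 reads, per chromosome, per 1 Mb and per 100 genes tested in the introgression lines. Shares have exact Clopper-Pearson intervals. Variants in RNA can be seen only where genes are expressed, so positions with few expressed genes have few records.

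Named genes followed a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in the higher line, no overlap between the lines' libraries and an informative description, the genes of a short list of single genes, members of gene lists, and the most abundant gene of each line. The identifiers are not paired with names or descriptions in the deposited tables and no annotation was used here, so the condition on descriptions was not applied, and only 2 identifiers that rose and 2 that fell are given. Solyc01g111170.2, Solyc12g095950.1 and Solyc09g097800.2 have the largest rise and the 2 largest falls in edgeR's fitted values, which for genes with 0 or 1 counts in a line rest on the prior count, so that the order of falls differs between tools and libraries left out, and Solyc02g085950.2 is both on the short list and the most abundant gene of IL2-6. Without the condition on descriptions, 5189 genes higher and 4406 genes lower in IL2-6 met the rule's other conditions. Identifiers at the borders of regions are given as positions. Gene lists defined by descriptions or identifiers were not tested for the same reason.

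Alternatives were other scalings (median-ratio size factors, upper quartile, TMM without chromosomes 2 and 3), other filters (none, or at least 1 CPM in 3 libraries), DESeq2, limma-voom, other thresholds, a replicate block and leaving out each library in turn. Thinning every library to the smallest total and a test against 2-fold (glmTreat) were added after the data had been seen.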

Results

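Leaf RNA was sequenced from field-grown tomato plants of the introgression lines IL2-6 and IL3-2, with 3 libraries per line, and from 1 library of the control M82. An introgression line carries a chromosome segment of a wild relative, here Solanum pennellii, in the background of a cultivated variety, and M82 is that cultivated background. IL2-6 is named for a segment of chromosome 2 and IL3-2 for a segment of chromosome 3. The labels describe IL2-6 as having enhanced biomass production. The IL2-6 libraries held 21320790, 18479252 and 20870366 gene counts in replicates 1, 2 and 3, and the IL3-2 libraries held 28828109, 32350234 and 40146308. The M82 library entered as a list of sequence variants with 48455 records. The labels do not say that the libraries of a line came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

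The comparison of IL2-6 with IL3-2 asked which leaf genes differ in abundance between the lines. Of 20823 genes tested, 6326 were higher in IL2-6 and 6865 were higher in IL3-2, together 13191 genes or 63.3% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 3 libraries per line). Among them, 3539 genes differed by at least 2-fold, and 2520 of these, or 71.2%, were higher in IL3-2 while 1019 were higher in IL2-6. Genes toward the end of chromosome 2 in identifier order and along much of chromosome 3, the chromosomes the lines are named for, passed this 2-fold limit more often than genes on the other numbered chromosomes. A stretch of chromosome 1 with counts in IL2-6 had none in IL3-2.

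The gene with the largest rise in IL2-6 was Solyc01g111170.2 on chromosome 1, with 1759 ± 61.2 CPM (counts per 1000000; SD, n = 3) in IL2-6 and no count in any IL3-2 library. Against a floor of 3 counts over the IL3-2 libraries, 0.028 CPM, it was at least 62700-fold higher in IL2-6 (edgeR adjusted p = 1.82e-16). Solyc02g085950.2 on chromosome 2, the most abundant gene of the IL2-6 libraries, had 27614 ± 531 CPM in IL2-6 and 6742 ± 815 CPM in IL3-2 (SD, n = 3 each). Its log2 fold change was 2.03 with a standard error of 0.07 (edgeR adjusted p = 4.75e-12). The most abundant gene of the IL3-2 libraries was also higher in IL2-6, at 20523 ± 847 against 13602 ± 558 CPM (SD, n = 3 each), a log2 fold change of 0.59 with a standard error of 0.04 (edgeR adjusted p = 2.78e-08).

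Solyc12g095950.1 and Solyc09g097800.2 had the largest falls in edgeR's fitted values over the 6 libraries, in an order that turned under DESeq2 (log2 fold changes of −11.89 and −12.73), limma-voom (−10.45 and −11.72) and without IL2-6 replicate 2 (−13.08 and −14.88). Solyc12g095950.1 on chromosome 12 had no count in IL2-6 and 36.8 ± 4.67 CPM (SD, n = 3) in IL3-2. It was at least 705-fold lower in IL2-6, against a floor of 3 counts over the IL2-6 libraries, 0.0522 CPM (edgeR adjusted p = 9.59e-12). Solyc09g097800.2 on chromosome 9 had 1 count in the IL2-6 libraries together and 13793 in the IL3-2 libraries, where its level was 128 ± 10.1 CPM (SD, n = 3). The ratio of the lines was 7391, with a 95% counting interval of 1326 to 291933 (edgeR adjusted p = 2.70e-15). The identifiers of the deposited tables are not paired there with gene names or descriptions, so these genes carry identifiers only.

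The lines stood apart by far more than libraries of the same line. Pearson correlations of log2 CPM across genes, which are not independent of each other, were 0.9923 to 0.9964 between libraries of 1 line and 0.8935 to 0.9019 between lines. The 10 most abundant genes took 9.12% to 9.46% of the counts in IL2-6 and 6.22% to 6.82% in IL3-2. With every library thinned to 18479252 counts, the smallest total, 23093 to 23103 genes had a count in IL2-6 and 24269 to 24301 in IL3-2. The labels of the IL3-2 libraries carry a lane and flow cell code and those of IL2-6 carry none, and they mention an unstranded single-end kit and a stranded paired-end kit without assigning them, so line and library batch cannot be told apart for single genes.

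The next comparison asked whether the differing genes gathered on the chromosomes that carry the named segments. On chromosome 3, 1557 of 2207 tested genes differed (70.5%), against 10092 of 16243 (62.1%) on the other 10 numbered chromosomes, an odds ratio of 1.46 (95% interval 1.32 to 1.61, two-sided Fisher's exact test p = 7.6e-15, adjusted p = 1.52e-14 over 4 tests). On chromosome 2, 1435 of 2226 genes differed (64.5%), an odds ratio of 1.11 (1.01 to 1.21, exact p = 0.0337, adjusted p = 0.0337). Among the 10 other chromosomes the share ran from 60.4% to 64.0%, and chromosome 2 lay just above the highest of them.

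The contrast was larger among genes that differed by at least 2-fold. These made up 25.1% of the tested genes of chromosome 3 (554 genes, odds ratio 1.83, 1.64 to 2.04, exact p = 1.85e-27, adjusted p = 7.4e-27) and 18.6% of those of chromosome 2 (413 genes, odds ratio 1.24, 1.11 to 1.40, exact p = 2.58e-04, adjusted p = 3.44e-04). The other 10 chromosomes held 2514 such genes, 15.5% of those tested, with a range of 13.6% to 16.8%. Genes not placed on a chromosome, which were left out of these tests, had a higher rate, with 58 of 147 at least 2-fold different (39.5%) and 107 called (72.8%). The tests treat genes as independent, which neighbouring genes are not, so these p-values are too small.

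Along chromosome 3, the excess ran from tested gene 41 to tested gene 1210 in identifier order, from Solyc03g005480.2 to Solyc03g098150.2. In this segment 414 of 1170 genes differed by at least 2-fold (35.4%), of which 214 were higher and 200 lower in IL3-2. On chromosome 2 it ran from tested gene 1861 to tested gene 2200 of 2226, from Solyc02g090020.2 to Solyc02g094350.2. There 115 of 340 genes differed by at least 2-fold (33.8%), of which 29 were higher and 86 lower in IL2-6. Of the 2-fold differences on the other 10 chromosomes, 73.0% were higher in IL3-2. That share was 74.8% in the chromosome 2 segment, close to this background, and 51.7% in the chromosome 3 segment, well below it. A scan for the block richest in such genes placed both segments, and none of 1000 shuffled gene orders gave as strong a block on either chromosome (permutation p = 0.001, the smallest that 1000 shuffles can give, adjusted p = 0.004 over 12 chromosomes). Shuffling treats neighbouring genes as independent, which they are not, so the scan's p-values are too small. Because the scan picks the richest block, the segments were also placed on alternate genes and measured on the genes between them. So measured, 384 of 1078 genes of chromosome 3 (35.6%) and 114 of 358 genes of chromosome 2 (31.8%) differed by at least 2-fold. Neighbours can change together, so the genes measured are not independent of those that placed the segments.

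In bins of 50 tested genes, those inside the chromosome 3 segment held a median of 17 genes of at least 2-fold (range 11 to 26, 23 bins) and those inside the chromosome 2 segment a median of 16 (range 12 to 21, 6 bins). The 320 bins of the other 10 chromosomes held a median of 7, with a 95th percentile of 13, and the richest of them, on chromosome 1, held 26. Outside the segments, the rest of chromosome 2 held 298 genes of at least 2-fold among 1886 (15.8%, odds ratio 1.02, 0.90 to 1.17, exact p = 0.712), and the rest of chromosome 3 held 140 among 1037 (13.5%, odds ratio 0.85, 0.70 to 1.03, exact p = 0.0913).

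**Figure D1:**
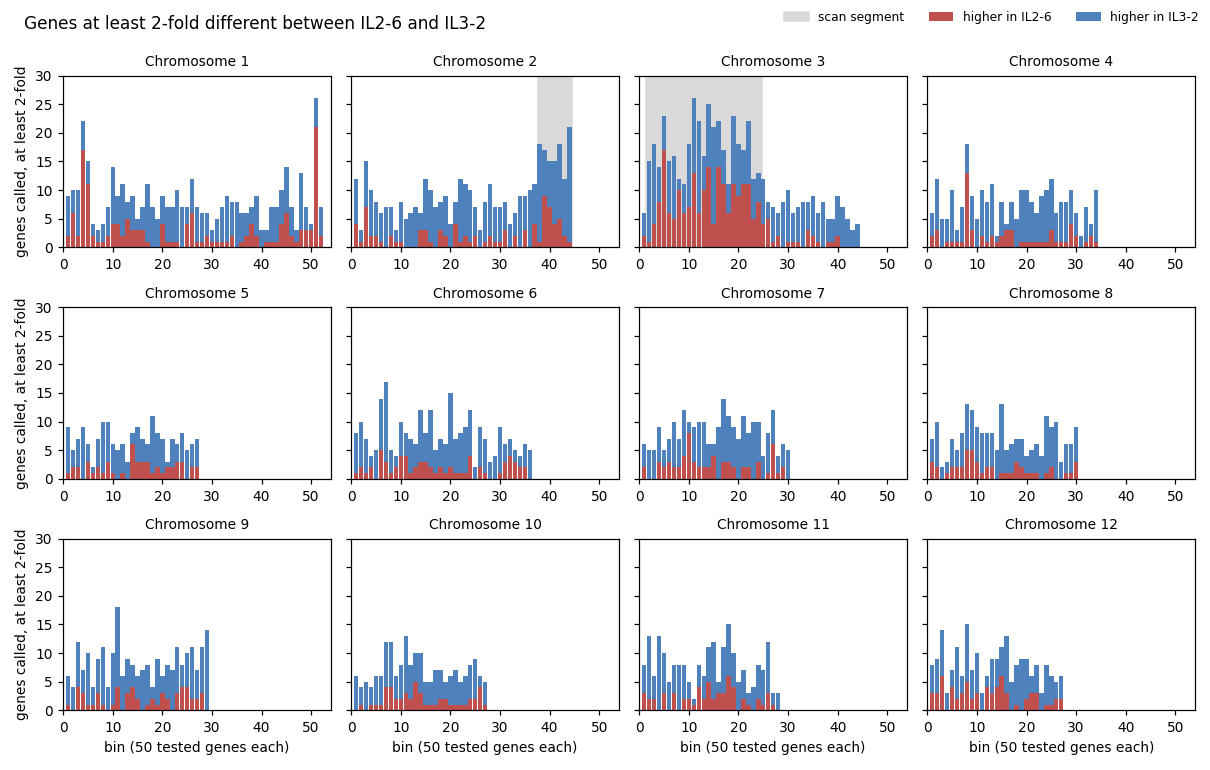
Genes that passed the edgeR test and differed by at least 2-fold between IL2-6 and IL3-2, in bins of 50 tested genes along the 12 chromosomes (x axis, bins in identifier order; y axis, genes per bin; red, higher in IL2-6; blue, higher in IL3-2; grey, segments placed by the scan). Bins in the grey segments hold 11 to 26 such genes, against a median of 7, a 95th percentile of 13 and a highest value of 26 in the bins of the other 10 chromosomes.

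Smaller blocks stood out on chromosomes that neither line is named for. On chromosome 1, tested genes 181 to 230 held 31 genes of at least 2-fold among 50, of which 27 were higher in IL2-6 (permutation p = 0.001, adjusted p = 0.004). The scan's log likelihood ratio was 27.1 for this block, close to the 27.3 of the chromosome 2 segment. So the scan did not single out chromosome 2. IL2-6 replicate 2 stood apart in this block, with a summed level of 9119 CPM against 3385 and 2637 in replicates 1 and 3. These sums used raw library totals and all listed genes between the borders of the block. Without replicate 2 the mean of IL2-6 fell from 5047 to 3011 CPM, against 519 in IL3-2, and 26 genes were at least 2-fold different, 22 of them higher in IL2-6. Blocks of 50 genes on chromosome 4 and of 110 genes on chromosome 6 held 20 and 34 such genes (adjusted p = 0.024 and 0.0264). The best blocks of the remaining chromosomes had adjusted p of 0.07 or above. All these p-values rest on shuffled gene orders and are likewise too small.

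Near the far end of chromosome 1, 53 successive listed genes, from Solyc01g110710.2 to Solyc01g111230.2, had no count in any IL3-2 library. In IL2-6, 22 of these genes had counts, 138247 in all, and 18 of them had at least 30. The remaining 31 genes had no count in any of the 6 libraries. Solyc01g111170.2 lies in this stretch, with 34969, 31354 and 34434 counts in the IL2-6 libraries. The listed genes on either side were counted in both lines. No other stretch without counts in a line covered more than 4 genes with at least 30 counts in the other line.

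**Figure D2:**
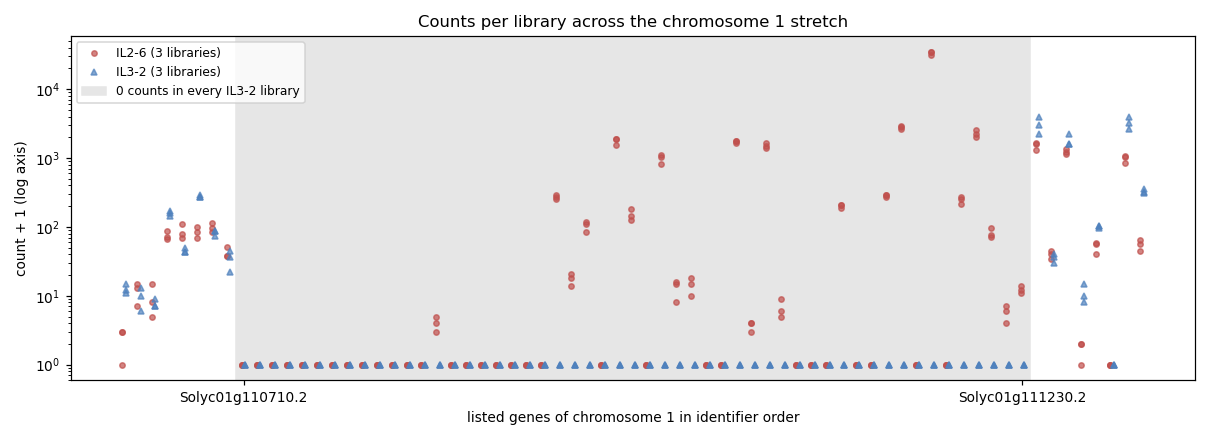
Counts per library, plus 1 on a log axis, for listed genes of chromosome 1 in identifier order (red circles, 3 IL2-6 libraries; blue triangles, 3 IL3-2 libraries; grey, the 53 genes without an IL3-2 count). In the grey stretch 22 genes have IL2-6 counts while every IL3-2 library is at 0, and both lines have counts on either side.

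The M82 library served, per the series description, as a genotype control through its variants. Of its 48455 records, 31694 were homozygous (65.4%, exact 95% interval 65.0% to 65.8%), and the median depth was 4 reads. Past a variant quality of 30 and a depth of 10 reads, 11309 records were left, 8068 of them homozygous (71.3%, 70.5% to 72.2%) and 3241 heterozygous, at a median depth of 27 reads. Homozygous records per 100 tested genes were highest on chromosome 5 (127.9), chromosome 4 (83.8) and chromosome 11 (66.2), against a median of 25.6 over the 12 chromosomes and 16.0 on chromosome 8, the lowest.

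The homozygous records were gathered in few places. The 20 richest of 781 bins of 1 Mb held 34.1% of the 7883 homozygous records on numbered chromosomes. The richest bins, in coordinates of the SL2.50 build that the file names, were 61000001 to 62000000 on chromosome 4 with 283 records, 55000001 to 56000000 on chromosome 4 with 278, 64000001 to 65000000 on chromosome 3 with 204, and 40000001 to 41000000 on chromosome 2 with 202. Chromosomes 2 and 3 as wholes held 25.5 and 32.9 homozygous records per 100 tested genes. There is 1 library and no replicate, the intervals cover counting error only, and genotypes of IL2-6 and IL3-2 were not analysed here.

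**Figure D3:**
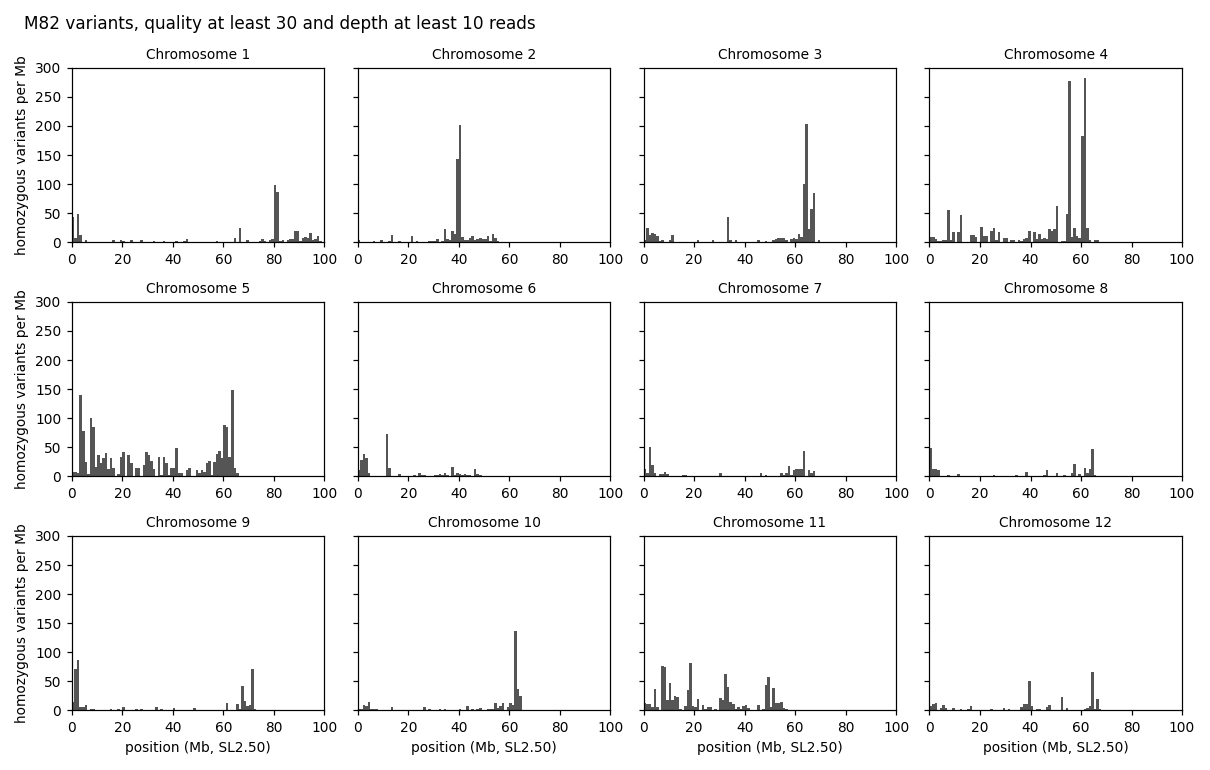
Homozygous M82 variants of quality 30 or more and depth 10 or more per Mb along the 12 chromosomes (x axis, SL2.50 position in Mb; y axis, variants per 1 Mb bin). The tallest bars are on chromosome 4, at 283 and 278 variants, and chromosome 5 carries variants along most of its length.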

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

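The thinning, the glmTreat test and the restriction to the scan segments were chosen after the results were seen. Over 10 results, 148 alternative values were computed, and 144 kept the direction and the side of the threshold, or for counts lay within 1.5 times the reported value. They include 15 values for each named gene, most of these genes being picked as extremes of the same data. Odds ratios of segments picked for their 2-fold calls are among them too. Such values had little room to change, so the 144 overstate how much was put to the test. The number of genes differing between IL2-6 and IL3-2 ran from 11970 to 13298 when each library was left out in turn and was 14266 without a filter. It was 3539 when a difference of at least 2-fold was required as well, by construction of that threshold. DESeq2 called 12276 genes, of which 11629 were among the 13191, and limma-voom called 13126, of which 13056 were. The share of calls higher in IL2-6 was 48.0%, and 46.4% to 48.5% under the other scalings.

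Tested against 2-fold with glmTreat, 645 genes were higher in IL2-6 and 1655 were higher in IL3-2, fewer than the 1019 and 2520 because the test asks for more than a point estimate past 2-fold. The odds ratio of calls ran from 1.10 to 2.05 on chromosome 2 and from 1.46 to 2.22 on chromosome 3 over 18 alternatives each, highest for the segments alone. The 4 named genes kept their direction and an adjusted p under 0.05 in all 15 settings that refit the genes. For those picked as the largest rise and falls, the choice all but fixed this outcome. The M82 records fell from 48455 to 11309 past the quality and depth minimums together, and which of these removed more was not tested.

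Libraries with the same replicate number did not deviate together (correlations of −0.119 to −0.008 over 3 pairs), so the numbers were not read as pairs. With the replicate number as a block, 12496 genes were called, 12463 of them among the 13191. Lists of genes by function, and the alternative without genes that overlap on opposite strands, were not run, since no annotation was used here. In the simulated counts, edgeR recovered 4 of 19 changes of 1.5-fold and 14 of 21 of 2-fold among the lowest of 3 equal groups of genes by level, against 24 of 24 and 25 of 25 in the highest, so small changes of low genes can be missed at this depth.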

Other observations

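The tests of thinning, the correlation with the level of neighbours and the correlation between adjacent genes were written down before their results were seen, although thinning was chosen after the difference in depth had been seen. The tests of batches, of scaling, of mapping in the segments and in the chromosome 1 stretch, of genes beside low neighbours, of splits of the libraries and of the stretch's depth and counting were chosen in their present form after the results they concern had been seen.

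Genes seen in 1 line only, with no count in any library of the other line and at least 10 in each of its own, were more frequent on chromosome 3. There 63 of 2207 tested genes were of this kind (2.85%), 43 seen in IL3-2 and 20 in IL2-6, against 193 of 16243 (1.19%) on the 10 chromosomes without a named segment, an odds ratio of 2.44 (1.8 to 3.28, two-sided Fisher's exact test p = 1.62e-08). Chromosome 2 held 16 of 2226 (0.72%, odds ratio 0.6, 0.34 to 1.01, exact p = 0.0536). In the segments, which were themselves picked for 2-fold differences, there were 58 of 1170 such genes on chromosome 3 (4.96%) and 1 of 340 on chromosome 2 (0.29%, odds ratio 0.25, 0.01 to 1.39). Of the 193 genes elsewhere, 155 were seen in IL3-2 and 38 in IL2-6. This rule used raw counts and the IL3-2 libraries were deeper, which favours genes seen in IL3-2 only, on chromosome 3 as well. The rule was not tried on thinned libraries. The 38 include neighbouring genes of the chromosome 1 stretch without IL3-2 counts, such as Solyc01g111170.2, which may not be separate observations.

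On the 10 chromosomes without a named segment, adjacent tested genes changed in the same direction more than by chance, with a Spearman correlation of log2 fold change of 0.083 over 16233 pairs, against at most 0.029 in 1000 shuffled orders. Runs of at least 4 adjacent genes that differed 2-fold in 1 direction numbered 17, of which 7 were higher and 10 lower in IL2-6, against a median of 2 and at most 8 in 200 shuffled orders. The longest run, 19 genes, overlaps the chromosome 1 stretch without IL3-2 counts. In the block of chromosome 1 at tested genes 181 to 230, the summed IL2-6 levels without the block's most abundant gene were 1214, 2734 and 1036 CPM in replicates 1, 2 and 3, against 518 ± 24.0 CPM (SD, n = 3) in IL3-2. In M82, heterozygous records past the minimum were most frequent on chromosome 8, at 34.3 per 100 tested genes against a median of 14.05, and 5 successive 1 Mb bins from 59000001 to 64000000 held 44 to 59 each.

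The share of 2-fold differences on chromosomes 2 and 3 was 21.8% of their genes together (exact 95% interval 20.6% to 23.1%). It was the highest of the 66 pairs of chromosomes (exact permutation p = 0.0152). The 45 pairs without either chromosome held at most 16.5%. But the pooled share rests mostly on chromosome 3, with 25.1%. Chromosome 2 held 18.6%, close to the 16.8% of the highest other numbered chromosome. For chromosome 3 the rank argues against a difference between library batches that has no tie to the chromosomes in the line names. For chromosome 2 it decides little, because chromosome 3 carries most of the pooled share. Loss of reads from wild alleles in mapping, without their being counted elsewhere, would add only genes lower in the line with the segment. But in segments placed on alternate genes and measured on the genes between, genes at least 2-fold higher in that line were in excess too. The odds ratio was 2.18 (1.44 to 3.18) on chromosome 2 and 1.71 (1.45 to 2.02) on chromosome 3. This argues against such loss as the whole cause. Whether reads of wild alleles were counted on near-identical copies was not tested. For genes lower in the carrier such loss may contribute. Genes at least 2-fold lower in the carrier were in excess, with an odds ratio of 2.37 (1.82 to 3.05) on chromosome 2. That was close to the 2.18 of genes higher in the carrier, with overlapping intervals. On chromosome 3 the odds ratio of genes lower in the carrier was 4.94 (4.13 to 5.9), above the 1.71 of genes higher in it. But the shares there were alike, at 17.7% lower and 17.9% higher in the carrier. On the other numbered chromosomes 4.2% were lower and 11.3% higher in IL3-2. The gap between the odds ratios comes from this unlike background, so it does not show that lower genes predominate on chromosome 3. The median log2 fold change, carrier minus other line, differed from that of the other chromosomes by −0.255 on chromosome 2 (−0.372 to −0.167) and −0.069 on chromosome 3 (−0.133 to −0.01). The intervals of these odds ratios and medians treat neighbouring genes as independent, which they are not, so they are too narrow. The small difference of medians on chromosome 3 is therefore uncertain. Wild alleles with other expression levels, the biological explanation that the design names, stay open beside such loss and were not tested apart.

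The excess of genes higher in IL3-2 among 2-fold differences was largest in genes of low level: 75.6% of 2509 such genes were higher in IL3-2 in the lowest of 3 equal groups by mean CPM (0.2 to 6.22), 67.9% of 669 in the middle group and 47.1% of 361 in the highest. Deeper IL3-2 libraries are argued against, since the share higher in IL3-2 stayed at 0.71 after thinning. A scaling error stays open for the excess as a whole. With a shift of −0.186 removed from every log2 fold change, the share would fall to 0.6. The other scalings gave shares of 71.0% to 72.0% and median log2 fold changes of −0.008 to −0.027, against −0.013 in the main fit. None came near that shift, but no outside standard shows whether it is there. For the contrast between levels a scaling error is argued against. The median of the lowest group less that of the highest, −0.346 (−0.374 to −0.322), is moved by no scaling factor. Reads of abundant neighbours counted on the wrong gene are argued against as the whole cause. Among low genes outside chromosomes 2 and 3 with both neighbours under 1 CPM, a share of 0.719 of 331 differences was still higher in IL3-2 (exact 95% interval 0.667 to 0.767). For a contribution by such reads, the correlation with the neighbour's level was compared with that with a gene 20 places away. It differed by −0.047 (−0.083 to −0.012), just short of the limit of −0.05 set beforehand for the value alone. By that rule it counted against a contribution. The interval spans the limit, a reading added afterwards, so a contribution was not settled. A difference between library batches cannot be told apart from the line, as 0 of the 3 IL2-6 labels name a flow cell, and a true difference between the lines stays open as well.

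The stretch of chromosome 1 without IL3-2 counts would have held 230884 counts in those libraries at the IL2-6 rate, so too few reads do not explain it. Loss of divergent wild alleles in mapping is argued against by the chromosome 3 segment, where only 0.2% of 491 genes with at least 1000 IL2-6 counts had none in IL3-2 (exact 95% interval 0.01% to 1.13%), while all 7 such genes of the stretch had none. Counting rules that differ between the lines, such as reads dropped where genes overlap, cannot be told apart from a biological loss over the 53 genes, because no coordinates or strands were used here. A deletion of this part of chromosome 1 in IL3-2 may be the biological counterpart, as a hypothesis that genomic reads over the stretch would test.

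For the 13191 genes called between the lines with edgeR, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many, the real one, and the highest of the others gave 0, with at most 279 genes at an unadjusted p under 0.05 against 13885. Every other split put libraries of both lines into each group, where the difference between the lines widens the spread. That left those splits little room to call genes, so the contrast with them says little. With 10 splits the share cannot go below 0.1, so the splits are too few for a share under 0.05.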
